A study of Mus musculus with 9 samples.

How the data were processed

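RNA from the aortas of 9 male C57BL/6J mice was measured on 9 one-colour arrays, 1 per animal, with 3 animals in each of 3 groups. The groups were vehicle, DIO (a high-fat diet for 4 months) and DIO+sitagliptin (high-fat diet-fed, with 3 mg/kg of oral sitagliptin per day). The treatment labels give no length of the diet for DIO+sitagliptin and name no diet for vehicle. Total RNA was converted to Cy3-labelled cRNA, per the labels' protocols. Each file holds the spots of 1 array as spot intensity, background-subtracted and spatially detrended by Agilent Feature Extraction 11.0.1.1, per the file headers. No normalization between arrays is recorded in the file headers. The scan records in the headers place 7 arrays on 12 November 2020 and 2 arrays, vehicle 3 and DIO+sitagliptin 3, on 20 November 2020. Of the arrays of 12 November, DIO+sitagliptin 1 has a scan hour of 18 and the others of 16. GEO types the series as sequencing, while the deposited files hold array intensities.

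The files list 61537 spots outside the control features, for 60823 different probes. Processed intensities were put on a log2 scale after adding 1, replicate spots of a probe were averaged, and the 9 arrays were quantile normalized. A fold change is therefore on the log2(intensity + 1) scale, which understates changes of dim probes. A probe was kept where at least 0.5 of its spots were marked as well above background in at least 3 of the 9 arrays, which left 49360 probes. Precision is limited by the number of arrays.

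Gene names were taken where the files pair a probe with a transcript accession, which was so for 50 probes printed as 10 spots each. RefSeq transcripts of GRCm38.p6 matched 46 of them and GENCODE transcripts 3 more, and 1 stayed without a symbol. The other probe identifiers were not matched to genes here and are used as printed. The headers name the mm9 build, so no coordinates are given. Control features entered no main comparison between groups, while a ratio of GAPDH control features was a covariate in an alternative fit. The files do not class the 15 probes named NEGATIVE and the 1092 named humanlincRNA as control features. Those that passed the detection filter were therefore tested.

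The groups were compared with limma 3.58.1 in R 4.3.3, in 1 fit of all 9 arrays with a coefficient per group, an intensity trend in the variance prior and no covariate. Benjamini-Hochberg adjustment ran over the probes of each comparison, and a probe was called at an adjusted p under 0.05 with no fold minimum. A moderated F-test compared all 3 groups. Intervals cover 95%. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for the control features and plots. The procedure was tested on simulated data for DIO against vehicle, with 49360 probes at their fitted spread and 50 probes changed at each size. It recovered 0% of the probes changed by 1 on the log2 scale, 8% of those changed by 2, 78% by 3 and 82% by 4, with 5 false calls. The simulated arrays were independent of each other, which the real arrays need not be.

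Before the data were examined, 28 gene lists (vascular cell types, vascular tone, incretin signalling, oxidative stress, lipid metabolism and others) and the rule for named genes were fixed. Of the 608 listed genes, 6 had a named probe and 3 of these were kept. A list was tested with camera (preset correlation 0.01, 1 probe per gene, among the 40 named genes kept) where at least 2 members had a kept probe, a minimum chosen after the number of named probes was known. The rule for a comparison in which no probe passes takes the 6 named rises and 6 named falls with the smallest unadjusted p, as values that did not pass, with the list members kept; 1 predicted gene was skipped. The rule also asks for Dpp4, Glp1r, Nos3, Edn1, Vcam1, Icam1, Ccl2, Adipoq, Lep, Ucp1, Acta2 and Pecam1, which no named probe covered and which were not analysed here.

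Alternatives covered the normalization, the intensity column, the pseudocount, the detection filter, leaving out each array, the arrays in the fit, the replicate number as a block, array weights, the variance prior, the call rule and the set test. Scan date, a ratio of GAPDH control features, a filter set by the probes named NEGATIVE, the median over spots, another weighting algorithm and the block within the 6 arrays compared were added after seeing the data. The labels give the groups the same replicate numbers. Deviations of same-numbered arrays from their group means correlated at 0.67, 0.65 and 0.76 between vehicle and DIO+sitagliptin, all over the limit of 0.1 for pairing. Vehicle 3 and DIO+sitagliptin 3 also share a scan date. The group means include these arrays, so a shift between scan dates adds to all 3 correlations. Between DIO and either of the other groups at least 1 pair was negative. Replicates are separate mice according to the series' design text. A result on 1 named probe is not reported here.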

Results

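Aortic RNA was profiled in vehicle mice, in mice made obese with a high-fat diet (DIO) and in DIO mice given sitagliptin. Sitagliptin is an oral inhibitor of DPP-4, the peptidase that inactivates incretin hormones such as GLP-1. By its title, the series asks how long noncoding RNAs and mRNAs of the obese aorta respond to the drug. The share of spots well above background ran from 61.7% to 82.9% per array, and the median spot intensity from 12.8 to 37.6 units. Probes named NEGATIVE in the array design, 45 spots per array, were themselves marked well above background in 22.2% to 71.1% of spots. Gene-level statements rest on 40 named genes. On each array between 16 and 24 of the 49 genes with a named probe were brighter than the highest NEGATIVE probe. Of the 40 genes, 14 stayed below it on all 9 arrays, among them Cpt1a, Gsta4, Gabrg1, Alkbh4, Cep41, Carhsp1, Ntng1, Trp53rka and E2f1, so that their differences are not separated from background.

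The arrays did not sort by treatment. The nearest neighbour of each array, by Pearson correlation over probes, belonged to another group in all 9 cases. As few own-group neighbours occurred in 52 of the 280 ways to split the arrays (one-sided exact permutation p = 0.186), with a mean of 2.25. Vehicle 1 was nearest to DIO 1 (r = 0.981 across probes, which are not independent replicates) and vehicle 2 to DIO 2 (r = 0.982). The mean correlation was 0.892 ± 0.077 (SD) over the 9 pairs within groups and 0.906 ± 0.067 over the 27 pairs between groups. The excess of within-group over between-group correlation was as high or higher in 220 of the 280 ways to split the arrays into 3 groups of 3 (one-sided exact permutation p = 0.786). These splits treat the 9 arrays as exchangeable. They take no account of scan date or of the deviations that same-numbered arrays share. Among the 7 arrays scanned on 12 November the means were 0.949 over 5 pairs within groups and 0.954 over 16 pairs between groups. The other 2 arrays, vehicle 3 and DIO+sitagliptin 3, correlated with each other at r = 0.934, and neither reached more than 0.864 with any array of 12 November. The first principal component held 59.9% of the variance, with scores of 214.1 and 234.8 for this pair against -132 to -25.3 for the others. No DIO array was scanned on 20 November.

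**Figure D1:**
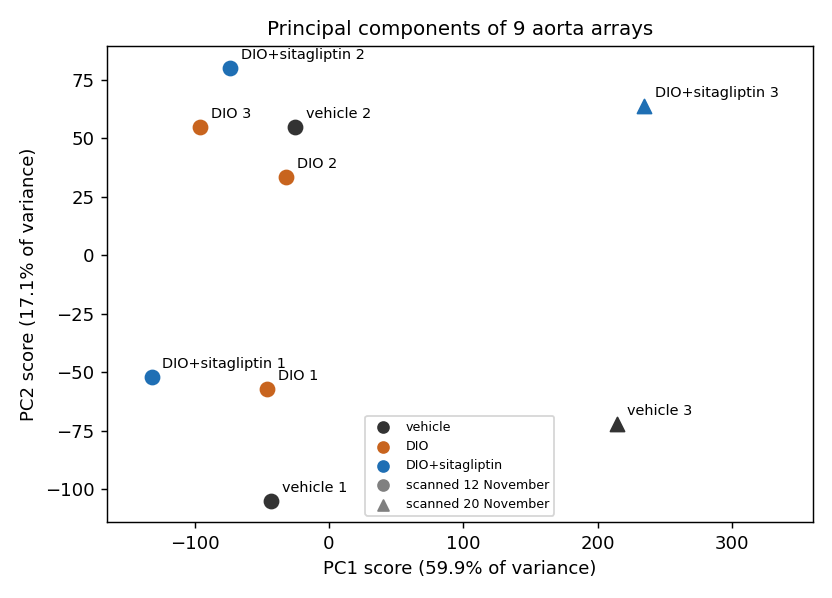
Scores of the 9 aorta arrays on the first 2 principal components of the 49360 kept probes, with colour for the group and marker shape for the scan date. Vehicle 3 and DIO+sitagliptin 3 lie at 214.1 and 234.8 on the first component, and the 7 arrays of 12 November lie at or below -25.3.

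The high-fat diet comparison set 3 DIO aortas against 3 vehicle aortas. The named genes furthest below vehicle in DIO were Actb, the cytoskeletal beta-actin, and H2-Q7, a class Ib histocompatibility gene. Actb differed by -2.29 ± 1.30 (SE, n = 3 per group; 95% interval -5.19 to 0.61) and H2-Q7 by -1.34 ± 0.85 on the log2 scale, both at a limma adjusted p of 0.925. Apoe, the apolipoprotein of remnant clearance, had a difference of -0.71 ± 0.71, H2-M2, a further histocompatibility gene, of -0.65 ± 0.52, Taf1a of -0.60 ± 0.44 and the odorant receptor Olfr166 of -0.73 ± 0.70. On the other side stood the T-cell growth factor Il2 with 0.74 ± 0.90, the plasma-cell chaperone Mzb1 with 0.47 ± 0.44 and Trp53rka with 0.43 ± 0.49. The GABA receptor subunit Gabrg1 had 0.39 ± 0.39, the granule protein Chgb 0.39 ± 0.57 and Gamt, an enzyme of creatine synthesis, 0.31 ± 0.46. Taf1a exceeded the highest NEGATIVE probe on 1 of 9 arrays and Chgb on 3 of 9, so their differences are hardly separated from background either. H2-Q7 exceeded it on 6 of 9 arrays and lay below it on vehicle 2, DIO 3 and DIO+sitagliptin 2. Il2 and Mzb1 exceeded it on 7 of 9 arrays each, and both lay below it on vehicle 3. The lower side of these 3 differences thus lies partly at background. No probe passed in this comparison, by limma at adjusted p under 0.05, and none did among the named genes adjusted alone, where the smallest adjusted p was 0.992. At an unadjusted p under 0.05 there were 354 probes, 215 higher and 139 lower, where 2468 of the 49360 tested would be expected without any change. That expectation, also used for the other comparisons, holds for independent arrays. Regrouping the DIO and vehicle arrays into other sets of 3 gave 207 to 4037 probes. The count of 354 depended on single arrays, 8 of which moved it by over 1.5 times. It was 83 without vehicle 3, 2350 without vehicle 2, 1299 without DIO+sitagliptin 3 and 492 with scan date as a term, with 0 calls in each case.

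For Actb and Apoe the spread within groups was as wide as these differences. Actb read 1903, 222 and 4287 intensity units in the 3 vehicle aortas and 1264, 131 and 73.9 units in the 3 DIO aortas. Apoe read 1110, 349 and 1184 units in vehicle and 855, 407 and 206 units in DIO. The mouse GAPDH control features whose names end in 3 and 5 also differed between arrays of 1 group. Their log2 ratio was -1.49, -0.02 and -2.47 in vehicle, -1.61, 0.43 and 0.15 in DIO, and -1.19, 0.49 and -1.73 in DIO+sitagliptin. The 4 arrays with ratios of -0.02 or more, 1 vehicle, 2 DIO and 1 treated, had normalized log2 Actb of 6.45 to 7.45. Of the other 5 arrays DIO+sitagliptin 3 had 7.39 and the remainder 9.53 to 11.97. Among the arrays of 12 November alone, 2 vehicle against 3 DIO, the Actb difference was -1.41, that of H2-Q7 -0.65, that of Apoe -0.37, that of Mzb1 0.05 and that of Il2 -0.00066. In the same arrays Taf1a stood at -0.10, Olfr166 at -0.28, H2-M2 at -0.34, Trp53rka at 0.07, Gabrg1 at 0.21, Chgb at 0.21 and Gamt at 0.23. Leaving out single arrays moved each of the 15 named values of this comparison by over 1.5 times. The arrays of 20 November hold 1 vehicle and no DIO aorta, so they give no value.

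Of the fatty acid oxidation list, 2 of 28 genes had a probe that was kept, and neither passed. Cpt1a, which admits long-chain fatty acids to mitochondria, had a difference of -0.41 ± 0.66 and Acaa2, the last enzyme of mitochondrial beta-oxidation, of -0.30 ± 0.51. The list of 2 genes did not pass (camera adjusted p = 0.519; adjusted p = 0.601 with an estimated correlation). Cpt1a read at most 16.1 units, below the highest NEGATIVE probe of each array, so the list rests on Acaa2. Prdx2, a peroxide-reducing peroxiredoxin and the member kept of the oxidative stress list, had 0.24 ± 0.46, which became -0.11 with median scaling alone. Cpt1a changed sign to 0.14 without the arrays of 20 November. The other 26 lists had no kept member. The Schwann cell and neuron list lost its 1 named gene to the detection filter. The rest had no named probe at all, so their genes could not be looked up here.

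The sitagliptin comparison set the 3 treated against the 3 untreated DIO aortas, which bears on the drug itself. Gpi1, the glycolytic glucose-6-phosphate isomerase, showed the lowest p among the named falls, at -0.997 ± 0.546 (SE, n = 3 per group; 95% interval -2.21 to 0.22; limma adjusted p = 1.000). Its log2 intensity was 5.14 ± 0.24 (SD) with the drug and 6.14 ± 0.999 without it. The treated aortas read 45.1, 38.5 and 30.6 units, where the highest NEGATIVE probes of these arrays read 48.6, 37.3 and 30.1, so the lower side of this difference lies at background. Acaa2 had a difference of -0.62 ± 0.51, Hspb7, a small heat-shock protein of muscle, of -0.62 ± 0.52, Tm9sf1 of -0.65 ± 0.51 and the RNA-binding Carhsp1 of -0.51 ± 0.40. Lhfp had -0.84 ± 0.67, where 1 of 10 spots on the DIO 2 array read 11312 units and the other 9 read 74 to 88 units. Higher values with the drug belonged to Gsta4, a glutathione transferase that clears lipid aldehydes, at 0.44 ± 0.33, the demethylase Alkbh4 at 0.44 ± 0.34, Duox1, a hydrogen peroxide-producing oxidase, at 0.59 ± 0.70, the peroxisomal Pex11a at 0.27 ± 0.44, Ntng1 at 0.26 ± 0.41 and Gabrg1 at 0.24 ± 0.39. Cpt1a differed by -0.03 ± 0.66 and Prdx2 by -0.21 ± 0.46. Single arrays moved 12 of these 14 values by over 1.5 times, all but Alkbh4 and Carhsp1. Without DIO 1 Hspb7 stood at -0.18 and Acaa2 at -0.35, and without DIO 3 Gpi1 at -1.57 and Gabrg1 at 0.02. Without DIO+sitagliptin 1 Tm9sf1 stood at -0.06 and Lhfp at -0.31, and without DIO+sitagliptin 3 Acaa2 at -0.29, Gsta4 at 0.20 and Ntng1 at 0.08. Tm9sf1 read 24.1 units on DIO+sitagliptin 1, below the highest NEGATIVE probe there. On DIO+sitagliptin 3 Acaa2 read 23.9 and Prdx2 24.2 units, also below it. No probe passed with limma, and 114 had an unadjusted p under 0.05, 73 higher and 41 lower, against 2468 expected without change. The number was 785 without DIO+sitagliptin 1, 434 without DIO+sitagliptin 2, 367 without DIO+sitagliptin 3 and 638 with scan date as a term, with 0 calls in each case.

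Within the arrays of 12 November, 3 DIO against 2 treated, Gpi1 had a difference of -1.14, while Duox1 stood at -0.23, Pex11a at -0.01, Prdx2 at 0.17 and Cpt1a at -0.55. The treated array DIO+sitagliptin 1 was scanned later that day than the others. Over 26 alternatives Cpt1a ranged from -0.85 to 0.30 here. Without both arrays of 20 November 1132 probes had an unadjusted p under 0.05. Arrays weighted by limma gave 680 calls in this comparison, 298 of them higher with the drug. In that weighting the array DIO+sitagliptin 2 carried a weight of 171 and the other 8 arrays weights of 0.10 to 1.36, and the estimation stopped before it converged. The fatty acid oxidation genes did not pass with the drug (camera adjusted p = 0.542; adjusted p = 0.601 with an estimated correlation). The median half-width of a probe's 95% interval, not adjusted for the number of probes, was 1.14 on the log2 scale. Changes near 2-fold could thus not be resolved for a typical probe. Adjusted calls miss larger changes too. In the simulation for DIO against vehicle they recovered 8% of the probes changed by 2 on the log2 scale and 78% by 3. That simulation drew independent arrays, without the scan date or the deviations that real same-numbered arrays share. Its shares therefore do not measure the recovery in the real arrays.

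Treated DIO mice were then compared with vehicle mice. Here 24 of the 40 named genes had lower and 16 higher mean intensities, and none passed. Gpi1 was lower in all 3 treated aortas than in any vehicle aorta, with a difference of -1.14 ± 0.55 (95% interval -2.36 to 0.07), although its treated readings lie at the level of the highest NEGATIVE probes. Apoe followed with -1.46 ± 0.71 (95% interval -3.04 to 0.13), H2-Q7 with -1.56 ± 0.85, Acaa2 with -0.92 ± 0.51, Actb with -2.37 ± 1.30 and H2-M2 with -0.80 ± 0.52. On the higher side were Gabrg1 with 0.62 ± 0.39, Cep41 with 0.36 ± 0.38, Alkbh4 with 0.25 ± 0.34, Gsta4 with 0.23 ± 0.33, the odorant receptor Olfr1307 with 0.20 ± 0.51 and Ntng1 with 0.15 ± 0.41. Cpt1a had -0.44 ± 0.66 and Prdx2 0.03 ± 0.46. Single arrays moved 11 of these 14 values by over 1.5 times, all but Gpi1, Apoe and Gabrg1. Without vehicle 3 H2-Q7 stood at -0.86, Actb at -1.48 and H2-M2 at -0.49, and without DIO+sitagliptin 3 Acaa2 at -0.59, Cep41 at 0.15, Gsta4 at -0.01, Olfr1307 at -0.15 and Ntng1 at -0.02. The groups did not overlap for 3 of the 40 genes (Gpi1, Gabrg1 and E2f1, the last named after its values were seen), where chance gives 10%, or 4 genes. Gabrg1, E2f1, Cep41, Alkbh4, Gsta4 and Ntng1 are among the genes that stayed below the highest NEGATIVE probe on all 9 arrays. H2-Q7 exceeded it on 6 of 9 arrays. The smallest adjusted p over the named genes alone was 0.815 and that over all probes was 1. No probe passed with limma, and an unadjusted p under 0.05 was reached by 713 probes, 394 higher and 319 lower, against 2468 expected without change. That number also depended on single arrays, 7 of which moved it by over 1.5 times. It was 328 without vehicle 1, 2523 without vehicle 2 and 5203 without DIO+sitagliptin 3, and 3393 with scan date as a term. Same-numbered arrays of these groups deviated together, and the 6 arrays with the replicate number as a block gave 3783 against 301 without it. Each of these settings had 0 calls. Among the arrays of 12 November, 2 against 2, Gpi1 differed by -1.11, Apoe by -0.94, H2-Q7 by -1.24 and Acaa2 by -0.35. The fatty acid oxidation genes did not pass (camera adjusted p = 0.519; adjusted p = 0.601 with an estimated correlation).

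**Figure D2:**
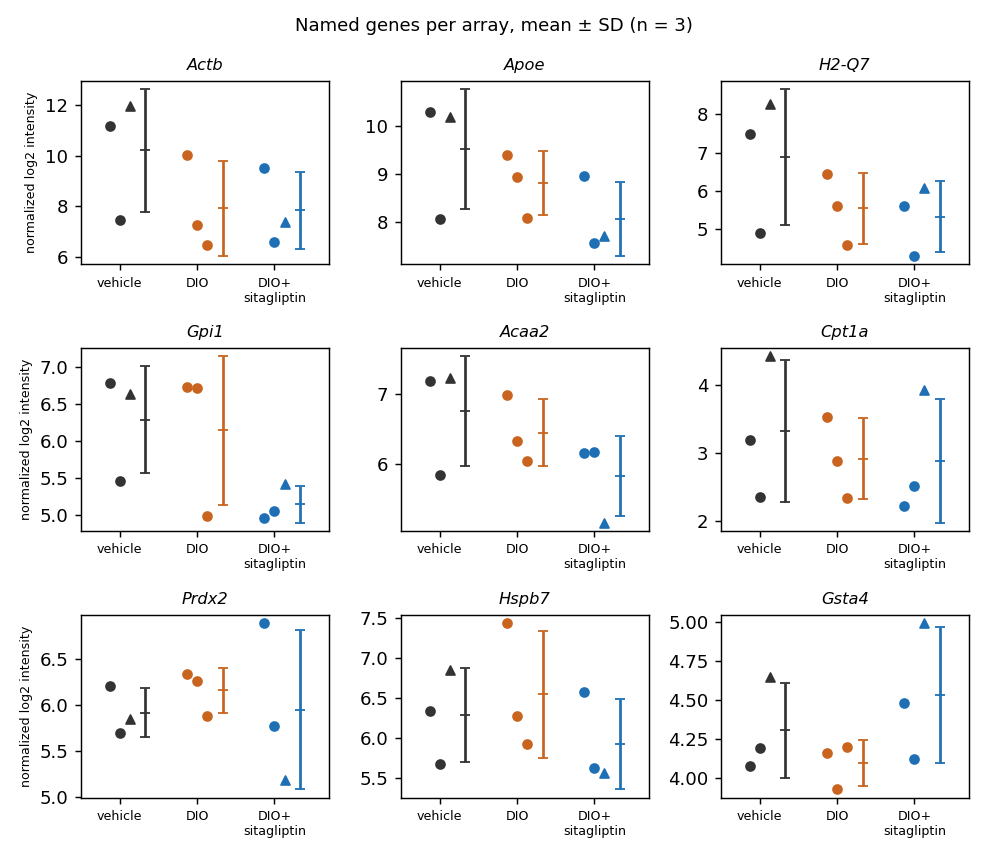
Normalized log2 intensity of 9 named genes on each array (circles, scanned 12 November; triangles, scanned 20 November), with the mean ± SD of each group of 3 beside the points. The groups overlap in each panel except Gpi1 in vehicle and DIO+sitagliptin, where the means are 6.29 and 5.14.

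Across all 3 groups the moderated F-test called 0 probes, with 211 at an unadjusted p under 0.05. The array weights that did not converge gave 5251 calls. Most probes carry the array maker's own identifiers. Of those beginning with ASMM10LNC 23503 were kept and of those beginning with ASMM10AP 18579, and both families had 0 calls. Their shares at an unadjusted p under 0.05 were 0.60% and 0.79% for DIO against vehicle, and 0.20% and 0.24% for DIO+sitagliptin against DIO. Among values that did not pass, the probe ASMM10AP1B106549116V4 had the smallest p of the probes higher in DIO than in vehicle, at 1.60 ± 0.43. The probe ASMM10UP689V4 had the smallest p of those lower with sitagliptin than in DIO, at -1.48 ± 0.46.

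Whether the drug moves transcripts back after the diet was addressed by setting both contrasts side by side. No probe passed both with opposite signs, and 0 passed both with the same sign. At an unadjusted p under 0.05, 8 probes met both with opposite signs and 0 with the same sign. Independent lists would share 0.818 probes of either sign. The real lists are not independent, since the shared DIO arrays alone favour opposite signs, so 0.818 is no reference for the 8. Simulated unchanged groups sharing the DIO arrays gave a mean of 567.4, with independent arrays drawn at each probe's fitted spread. The real lists held 354 and 114 probes, so their overlap could not reach 567.4, which is no reference for it. The covariance of the log2 fold changes was -0.15 (r = -0.59 across probes). Both contrasts use the same 3 DIO arrays, and unchanged groups simulated with each group's own spread gave a covariance of -0.08, while a pooled spread gave -0.22. The difference from simulation was -0.07 in the first case and 0.07 in the second, so its sign depended on the spread assumed. Both covariance simulations also draw the 9 arrays independently. Vehicle 3 and DIO+sitagliptin 3 share a scan date, and vehicle and treated arrays of the same number deviate together, so neither simulation is a full reference. Without the arrays of 20 November the covariance was 0.00035. The 3 DIO arrays were too few to split between the contrasts, so what the shared arrays add to the covariance was not separated.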

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

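All tests of explanations in this part were chosen after the values were seen, as was the grouping of splits by pairs or scan date, while the counts of calls over other splits of the arrays were planned.

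Of the control features outside the comparisons, those named GAPDH_3 for mouse had a mean above the highest NEGATIVE probe on each of the 9 arrays. The ratio was lowest on DIO+sitagliptin 1, at 1.09. The median of the E1A control features stayed below the highest NEGATIVE probe on all 9 arrays.

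Vehicle 3 and DIO+sitagliptin 3 stood apart from the other arrays. Treatment as the source is argued against by their closest match within their own groups, r = 0.864, below the r = 0.934 they share with each other. That higher value is what a difference between scan dates predicts. The prediction was written after the pair was seen to stand apart, so the value is no independent test of it. The headers give vehicle 3 the position 2_3 and DIO+sitagliptin 3 the position 2_2. DIO+sitagliptin 1 and DIO 3 hold the same positions on 12 November. If these are places on a slide, the later pair was hybridized on another slide. The headers do not tell whether animals, RNA, labelling or the day of hybridization differed, and DIO has no array from the later day. NEGATIVE probes had median intensities of 1.22 and 1.29 units on this pair against 7.84 to 26.7 on the other arrays.

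Actb, a gene often used as a reference, spanned 58.0-fold over the 9 arrays, with large gaps inside each group. Overall brightness is argued against, since 94.6% of its log2 range was left after quantile normalization. The high-fat diet is the same for all mice of a group, so gaps inside a group cannot test it. The smallest log2 range inside a group, 2.94, exceeded the difference of 2.29 between the DIO and vehicle means, which decides nothing about diet. Whether diet adds to that difference of means is not resolved. RNA integrity stays open, since the GAPDH log2 ratio, read as a 3′ to 5′ ratio, falls into sets of 5 and 4 arrays with a gap of 1.17 between them, so no correlation with Actb was computed. Actb was low on the 4 arrays with high ratios and on DIO+sitagliptin 3, whose ratio is low.

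Lhfp on DIO 2 averaged 1203 units against 37.5 to 162.1 on the other 8 arrays. More transcript in that animal is argued against, because 1 of its 10 spots lay above the highest spot of the other arrays. The median of its spots, 80.4 units, lay within the 37.7 to 160.8 of the other medians, consistent with a single aberrant spot. With medians over spots the difference between DIO+sitagliptin and DIO was -0.60.

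Other splits of the arrays were counted for each comparison. The 10 splits of 3 against 3 are too few for a share under 0.05, and all 10 reach a count of 0 by construction. The real count was 0 in each comparison, and the highest other count was 0 for DIO against vehicle, 0 for DIO+sitagliptin against DIO and 1 for DIO+sitagliptin against vehicle. For the 3 groups together, 100 of the 280 splits were drawn, and a real count of 0 is reached by all 100 by construction, so this count decides nothing. The highest other split called 264 probes, which points to a structure of the samples. It joined vehicle 1, DIO 1 and DIO+sitagliptin 1, placed both arrays of 20 November with vehicle 2, and left DIO 2, DIO 3 and DIO+sitagliptin 2. Splits that kept both arrays of 20 November together had a median of 9684.5 probes at an unadjusted p under 0.05, against 573.5 for those that parted them. For DIO+sitagliptin against vehicle, the real split had 713 probes at an unadjusted p under 0.05. The 3 others that part all same-numbered pairs had 203 to 472, and the 6 that keep a pair together 410 to 15784. Of all 10 splits, 6 reached 713, the real one among them. For DIO against vehicle, 5 of 10 reached the real 354, with the others at 207 to 4037. For DIO+sitagliptin against DIO, all 10 reached the real 114, with the others at 245 to 4137. With scan date as a term, the counts of calls in the 3 comparisons stayed at 0.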

How the results depend on the processing

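Scan date, the GAPDH ratio, the NEGATIVE-probe filter, the median over spots, gene-by-gene weights, the block within 6 arrays and camera against all kept probes were chosen after seeing the data. Of 29 alternatives, 27 gave 0 calls for probes in each comparison they could test, the replicate block among them, and the counts of gene lists were 0 in all 29 run for them. Array weights gave 680 calls for DIO+sitagliptin against DIO, 5251 over the 3 groups and a covariance of 0.0309; 1 array then had a weight of 171 without convergence, and the gene-by-gene algorithm (largest weight 3.08) gave 0 calls. An unadjusted p under 0.05 with a 2-fold change gave 260, 64 and 469 probes in the order DIO against vehicle, DIO+sitagliptin against DIO and DIO+sitagliptin against vehicle, 181 over the 3 groups and 3 with opposite signs, by its own construction.

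The replicate block, the fit without an intensity trend and the other call rule cannot move the covariance of -0.15. With these counted, the covariance was negative under 22 of 26 alternatives, a sign that simulated unchanged groups also gave. It was -0.0783 with median signal, -0.0918 with a pseudocount of 16, -0.0134 with a scan date term, -0.0455 with scan date and replicate block, -0.0180 with scan date and GAPDH ratio, 0.0112 with gene-by-gene weights and 0.00035 without both arrays of 20 November. Leaving out 1 array gave -0.26 (without DIO+sitagliptin 1) to 0.0572 (without DIO+sitagliptin 3); without vehicle 3 it was -0.04. These values tie it to the arrays of 20 November; for the other settings the cause was not tested. Same-numbered arrays deviated together between vehicle and DIO+sitagliptin. Over all groups 6 of 9 pairs were over 0.1 (-0.34 to 0.76) and 7 of 9 arrays correlated best with their own number. Structure by number was not separated from the scan date that vehicle 3 and DIO+sitagliptin 3 share. With the replicate block no call changed: the counts stayed at 0 in the 3 comparisons.

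Of 1175 named-gene values under alternatives, 14 moved by more than the replicate SD, 55 had the other sign and 0 passed (smallest limma adjusted p 0.058). Part of the 1175 cannot move, such as values without an array outside the comparison or with the replicate block. The replicate SD is wide where arrays of a group lie apart, so a large shift can stay within it. Single arrays moved 15 of 15 values by over 1.5 times for DIO against vehicle. They moved 12 of 14 for DIO+sitagliptin against DIO and 11 of 14 for DIO+sitagliptin against vehicle. Median scaling shifted the median log2 difference of DIO against vehicle from 0.05 to -0.10. Each named gene had 1 probe, so averaging probes per gene was not run. Signal over background limits dim probes: 28397 of all 60823 probes exceeded the highest NEGATIVE probe in at least 3 arrays, where 49360 passed the detection filter.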

Other observations

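These values were picked after they were seen. The probe for Lhx1, a transcription factor of kidney and limb patterning, read 313 and 629.2 units on vehicle 3 and DIO+sitagliptin 3 and 83.6 to 208.3 units on the other arrays. The odorant receptor probe Olfr166 read 382.2 and 571.8 units on the same pair and 78.5 to 264.7 units on the others. Among probes left out as too dim were those of Ppara, a lipid-sensing nuclear receptor, seen in 2 of 9 arrays, Cav2, a caveolar coat protein, in 0, and the named Sod1 transcript, in 1.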
